A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

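PolyA RNA of Saccharomyces cerevisiae was labelled with Cy5 after 2 h in 1 of the 3 nitrophenol isomers and with Cy3 before treatment, and both were hybridised to 1 array per culture, per the labels. The labels give 3 independent biological samples for each isomer, 9 arrays in all, and do not say whether the RNA taken before treatment was shared between arrays. Each array was scanned at high and low laser power (18 columns of values), so a scan is not a replicate and n is 3 arrays per isomer.

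The deposited values are log2 ratios, normalized by the authors with LOWESS using spots whose flag was 0, per the labels. The log2 scale was settled from the values, since 13 lie at exactly the log2 of 0.01, a lower limit of the ratio. The direction is not stated with the values, and treated over untreated is likely from the channel order and dyes in the labels. The labels also name a merge of the high- and low-power scans in GeneSpring, which is not used here. Background correction is not given in the sources used here, and no spot intensities were analysed here, so signal over background and saturation could not be examined. The column medians, high and low power in turn, were 0.05 and 0.10, 0.09 and 0.08, and 0.08 and 0.08 for the 3 p-nitrophenol arrays, 0.00 and 0.01, 0.10 and 0.08, and 0.10 and 0.12 for the m-nitrophenol arrays, and -0.13 and 0.05, -0.01 and -0.04, and -0.02 and -0.05 for the o-nitrophenol arrays. A scan held values for 766 to 6080 of the 6912 probes. Which spots lack a value was decided before deposit by rules not given in the sources used here, and missing values can favour bright spots.

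Of the probes, 5513 had 1 gene symbol in an older annotation of the array, 1399 had none and 0 had several. Symbols were updated through Entrez identifiers with a RefSeq table of the R64 assembly, where 5360 of 5365 genes matched. No genome build is named with the values, so no coordinates are given. Probes of a gene were averaged, which concerned 99 genes.

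The log2 ratios of both scans of an array were averaged, or the single scan with a value was taken, and limma 3.58.1 in R 4.3.3 fitted a group-means model to the 9 arrays, with 6 residual and 4.409 prior degrees of freedom. Genes with a value on at least 2 arrays of each group were tested, 5096 in all. Each isomer was tested against 0, which includes 2 h of growth and any dye effect, and the isomers were then tested against each other in pairs and by a moderated F test. limma's F takes the correlation of its contrasts from complete values, so it was also computed from each gene's own numbers of arrays. Benjamini-Hochberg adjustment was made within each contrast, and the threshold was an adjusted p of 0.05. The spread is shared by the 3 groups, with median standard errors of 0.345, 0.378 and 0.352 for the p-, m- and o-nitrophenol means.

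Data were simulated with the real missing values and 1 spread per gene, with 50 genes changed per size. Noisier arrays numbered 1 and deviations shared by arrays were not simulated. At a log2 change of 2, 88%, 62% and 72% were called for p-, m- and o-nitrophenol, and 10%, 12% and 12% at 1. For m minus p, o minus p and o minus m 24%, 32% and 24% were called at 2 and 90%, 80% and 90% at 4. Of 4896 unchanged genes 3 to 12 were called.

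The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from 3 alternatives named in the account of the processing. In each treatment the 10 largest positive and 10 largest negative means were named among genes past the threshold with a standard name and 1 sign on 3 measured arrays, and in each isomer difference up to 6 in each direction whose arrays did not overlap. Up to 4 members of a described list and 13 further genes (PDR5, SNQ2, YHB1, FRM2, HBN1, OYE2, OYE3, HSP12, HSP26, TRX2, GTT2, RPN4 and PMA1) were given by the same rule. URA1 between m- and p-nitrophenol, and genes of the closing observations, were chosen after their values were seen. Genes without a standard name, 71 higher and 25 lower in p-nitrophenol, 44 and 14 in m-nitrophenol and 73 and 45 in o-nitrophenol, were counted but not named by this rule.

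36 gene lists were written from textbook knowledge, and each had at least 5 measured members. They were tested against all other genes with camera at a preset correlation of 0.01 and again with a correlation estimated from the members on all 9 arrays, where negative estimates were set to 0 and lists with too few members on all 9 arrays had none. fry, which asks only whether a list moves on balance in 1 direction, was run on the 1757 genes with values on all 9 arrays. Where a list passed camera, its median, its mean and the test had the same sign.

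Alternatives were the high-power or low-power scans alone, all scans with the array as a random block (statmod 1.5.0, correlation 0.888), centring, scale and quantile normalization between arrays, no filter, genes with both scans of all 9 arrays, probes of one gene not averaged, array weights, a robust prior, the arrays of each contrast alone, a replicate block and each array left out in turn. Leaving out 1 of 3 arrays left 2 for genes with 3 values and 1 for some (most in m-nitrophenol without array 2 or 3), which is assumed to vary like the others. The labels do not say whether a replicate number marks a shared day. Deviations from the group means of same-numbered arrays correlated over 0.1 in all 3 pairs of p- and o-nitrophenol (0.3327, 0.2885 and 0.2275), so the numbers are taken to pair these arrays. In the pairs with m-nitrophenol 3 of 6 did (0.0382 to 0.2425). Splits of the arrays into other groups were counted, 100 of 280 and 36 that part same-numbered arrays for the F test, all 10 for each pair and all 15 of arrays 2 and 3 alone.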

Results

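Transcript levels of budding yeast (Saccharomyces cerevisiae, strain background S288C) were measured before and after exposure to each of the 3 isomers of nitrophenol, a phenol ring that carries a nitro group. Cultures in YPD, a rich glucose medium, at 25 °C and an optical density of 1 received p-nitrophenol at 1.5 mM, m-nitrophenol at 5 mM or o-nitrophenol at 3 mM for 2 h. Each isomer had 3 independent biological replicates, each hybridised to 1 2-colour array, 9 arrays in all. On every array the treated RNA carried Cy5, and RNA of the same strain from before treatment Cy3. Each array was scanned at high and low laser power (18 scans). The values are log2 ratios, and a positive value is read as higher after treatment. That direction is likely from the channel order and dyes in the labels, but not stated with the values. The comparisons ask which genes respond to each isomer and where the responses differ.

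The arrays did not measure the same number of genes. Values were present for 4369, 5247 and 5252 genes on p-nitrophenol arrays 1, 2 and 3, for 1970, 5333 and 5343 on the m-nitrophenol arrays, and for 3797, 5316 and 5155 on the o-nitrophenol arrays. Of 5365 named genes, 5096 had values on at least 2 arrays of every group and were tested, and 1757 had values on all 9. Most m-nitrophenol means rest on 2 arrays (1959 tested genes had 3), and on 1 in fits without array 2 or 3, which alone can lower counts. The arrays numbered 1 stood apart in each group. Across genes they correlated with the others of their group at r of 0.51 to 0.61, and arrays 2 and 3 with each other at 0.84 to 0.88 (genes are not independent replicates). Gene values below are group means of log2 ratios ± the standard error of the limma fit, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. The number of arrays limits the precision. The median 95% half-width was 0.78, 0.85 and 0.80 for the p-, m- and o-nitrophenol means, and 1.15, 1.12 and 1.17 for the m minus p, o minus p and o minus m differences. Medians of gene lists are given relative to the median of all tested genes in the same contrast, which was 0.10 for p-nitrophenol, 0.04 for m-nitrophenol, -0.17 for o-nitrophenol, -0.05 for m minus p, -0.20 for o minus p and -0.13 for o minus m. Centring each array on its median moved the median of all genes by 0.16 in o-nitrophenol, 0.26 in o minus p and 0.22 in o minus m. Quantile scaling moved them by 0.13, 0.14 and 0.12. The arrays hold no untreated culture at 2 h and no swapped dyes, so growth and dye effects are part of each treatment contrast, while the part common to all arrays cancels between isomers.

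After 2 h in 1.5 mM p-nitrophenol, 661 of the 5096 genes were higher and 606 lower than before treatment, 570 and 563 of these by at least 2-fold. The 10 largest rises and falls of each isomer are named here among genes with a standard name and values on all 3 of its arrays. CIS1 rose by 4.80 ± 0.80 and GRE2, a methylglyoxal reductase, by 4.63 ± 0.90 on the log2 scale. PDR5, the main ABC drug efflux pump of the plasma membrane, rose by 3.64 ± 0.40, and SNZ1, of pyridoxine synthesis, by 3.76 ± 0.41. The cell wall mannoprotein gene SRL1 fell by 5.67 ± 0.25 and GUA1, which encodes GMP synthase, by 4.68 ± 0.35. Ribosomal protein genes RPL5, RPL4A, RPL4B, RPL30, RPL3 and RPS7A were also among the 10 largest falls, with means from -4.43 to -4.03, as were NSR1, a nucleolar protein gene (-4.52 ± 0.58), and INA1 (-4.22 ± 0.48). The other large rises were GPG1 (3.88 ± 0.56), the vesicle SNARE gene SNC2 (3.50 ± 0.27), the serine and threonine deaminase gene CHA1 (3.27 ± 0.89), the stress gene DDR2 (3.16 ± 0.69), FMP23 (3.13 ± 0.34) and the methyltransferase gene TMT1 (3.07 ± 0.44). All 20 had the same sign on all 3 p-nitrophenol arrays, with adjusted p from 9.03e-06 for SRL1 to 0.0243 for CHA1.

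camera was also run with the correlation r between genes estimated. Ribosomal protein genes had the lowest list median in p-nitrophenol. 94 of 124 cytosolic ribosomal protein genes fell (110 adjusted within the list). Their median was -2.44 (camera adjusted p = 1.13e-32, 0.339 with estimated r). 23 of 42 ribosome biogenesis genes fell (28 adjusted within the list), NOP1 by 3.71 ± 0.30 among them. Their median was -1.53 (camera adjusted p = 8.6e-11, none with estimated r). 14 of 26 translation factor genes fell and 1 rose (17 and 1 adjusted within the list). The elongation factor genes EFT2 and YEF3 fell by 3.57 and 3.77, and the list median was -1.54 (camera adjusted p = 2.04e-06, 0.339 with estimated r). 11 of 21 purine and pyrimidine synthesis genes fell and 2 rose (15 and 2 adjusted within the list), with a median of -1.52 (camera adjusted p = 1.33e-05, 0.162 with estimated r). The IMP dehydrogenase gene IMD2 fell by 3.95 ± 0.38, while URA1, dihydroorotate dehydrogenase, rose by 2.69 ± 0.28. 13 of 24 ergosterol synthesis genes fell (15 adjusted within the list). ERG11, the azole target, fell by 2.81 ± 0.38, and the median was -1.29 (camera adjusted p = 2.79e-06, 0.101 with estimated r). 10 of 29 cell cycle genes fell (10 adjusted within the list). The ribonucleotide reductase gene RNR1 fell by 3.60 ± 0.31 and the G1 cyclin gene CLN2 by 3.05 ± 0.34, with a list median of -0.78 (camera adjusted p = 0.000184, 0.0988 with estimated r). 8 of 25 cell wall genes fell and 2 rose (11 and 2 adjusted within the list), with a median of -0.64 (camera adjusted p = 0.00572, 0.63 with estimated r). The mannoprotein gene TIR1 fell by 4.03 ± 0.49 and the glucanosyltransferase gene GAS1 by 3.15 ± 0.36. 6 of 14 mating genes fell and 2 rose (6 and 2 adjusted within the list), with the agglutinin gene SAG1 at -3.73 and a median of -0.84 (camera adjusted p = 0.0127, 0.215 with estimated r). 8 of 19 phosphate response genes fell and 1 rose (10 and 1 adjusted within the list). The transporter gene PHO84 fell by 2.88 ± 0.42, and the median was -0.84 (camera adjusted p = 0.00124, 0.339 with estimated r). 7 of 25 polyamine, weak acid and ion homeostasis genes fell and 1 rose (12 and 2 adjusted within the list). The polyamine exporter genes TPO2 and TPO3 fell by 2.60 and 2.29, and the list median was -0.90 (camera adjusted p = 0.0179, 0.226 with estimated r). 7 of 24 nitrogen catabolism genes fell and 2 rose (8 and 2 adjusted within the list). The amino acid permease gene AGP1 fell by 2.20 ± 0.29, and the median was -0.44 (camera adjusted p = 0.0484, 0.215 with estimated r). In glycolysis 2 of 23 genes fell (2 adjusted within the list), ADH4 and PFK2, with a median of -0.63 (camera adjusted p = 0.021, 0.491 with estimated r).

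6 lists lay above the other genes in p-nitrophenol. 7 of 16 aryl-alcohol and aldehyde dehydrogenase genes rose (9 adjusted within the list). The aldehyde reductase gene ARI1 rose by 2.90 ± 0.38 and AAD4 by 2.77 ± 0.49, and the median was 1.39 (camera adjusted p = 0.00107, 0.101 with estimated r). The AAD genes are near-identical copies, so that a probe can read several of them. 13 of 37 proteasome genes rose (15 adjusted within the list), RPN12 by 1.63 ± 0.23 and SCL1 by 1.82 ± 0.35 among them. Their median was 0.63 (camera adjusted p = 5.06e-05, 0.608 with estimated r). 7 of 19 autophagy and vacuolar proteolysis genes rose (11 adjusted within the list). ATG8, the ubiquitin-like protein of autophagosomes, rose by 2.80 ± 0.53, and the median was 0.71 (camera adjusted p = 0.0018, 0.215 with estimated r). 6 of 31 sulfur amino acid genes rose (3 adjusted within the list). The cystathionine beta-lyase gene STR3 rose by 4.68 ± 0.64 and MET17 by 2.57 ± 0.66, and the median was 0.84 (camera adjusted p = 0.00942, 0.703 with estimated r). 10 of 26 iron uptake genes rose and 2 fell (10 and 2 adjusted within the list), with a median of 0.92 (camera adjusted p = 0.0188, 0.485 with estimated r). The copper pump gene CCC2 rose by 1.74 ± 0.25, and FRE1, a metal reductase, fell by 1.75 ± 0.37. 9 of 19 diauxic shift markers rose and 1 fell (9 and 1 adjusted within the list), with a median of 1.12 (camera adjusted p = 0.0196, 0.63 with estimated r). SNZ1 and SNO1, both of pyridoxine synthesis, had the lowest p. The remaining 18 lists did not pass in p-nitrophenol. Their medians were 0.08 for multidrug resistance (adjusted p = 0.481), 0.03 for oxidative stress (0.172), 0.48 for nitroreductase-like enzymes (0.317), 0.04 for heat shock proteins (0.493), 0.62 for the general stress response (0.221) and -0.66 for trehalose and glycogen (0.158). Lipid and carbon lists gave -0.34 for the unfolded protein response (0.219), 0.20 for fatty acid and phospholipid synthesis (0.879), -0.07 for beta-oxidation (0.879), -0.53 for the TCA cycle (0.219), -0.22 for respiration (0.227) and -0.31 for hexose transport (0.493). The others gave -0.35 for Gcn4-controlled amino acids (0.304), -0.21 for aromatic amino acids (0.54), -0.03 for copper and zinc (0.501), 0.16 for DNA damage (0.842), -0.01 for meiosis (0.493) and 0.35 for thiamine, pyridoxine and biotin (0.219). On array 1 the general stress list had a median of 2.57 against -0.44 and -0.26 on arrays 2 and 3, and the sulfur list -0.43 against 1.47 and 1.21. Without replicate 2 of p-nitrophenol 211 genes were higher and 288 lower, and without replicate 3 the numbers were 259 and 308. The calls of GRE2 (without replicate 2, adjusted p = 0.0516), DDR2 (without 1, 0.0584), CHA1 (without any, 0.0659 to 0.117), sulfur (without 2 or 3, 0.0839 and 0.0673), glycolysis (without 2 or 3, 0.0657 and 0.0809), iron (without 1, median 0.56, 0.102) and the diauxic list (without 1, median 0.22, 0.216) ended, as did nitrogen catabolism without p-nitrophenol replicate 2, o-nitrophenol replicate 1 or any m-nitrophenol array (0.0509 to 0.144), while its median was -0.76 without p-nitrophenol replicate 3. Without the 3 arrays numbered 1, an alternative chosen after seeing the data, 1150 genes were higher and 996 lower, 623 and 579 of them shared with the fit of all arrays, the diauxic (0.292) and nitrogen (0.0745) calls ended, and trehalose (median -1.38, adjusted p = 1.53e-05), the TCA cycle (-0.94, 0.049) and hexose transport (-0.48, 0.0171) passed.

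After 2 h in 5 mM m-nitrophenol, 421 genes were higher and 492 lower, 402 and 480 of these by at least 2-fold. The transaldolase gene NQM1 rose by 4.92 ± 0.93, GRE2 by 4.60 ± 0.90, GPG1 by 4.23 ± 0.56, and HSP26, a small heat shock protein gene, by 4.10 ± 1.15. PDR5 rose by 3.51 ± 0.40 and SNZ1 by 3.39 ± 0.41, and the other large rises were FMP16 (3.52 ± 1.00), the membrane stress protein gene HSP12 (3.41 ± 0.59), the proteinase inhibitor gene PBI2 (3.40 ± 0.53) and ATG8 (3.12 ± 0.53). All 10 of the largest falls among genes measured on 3 arrays were ribosomal protein genes, from RPL4A at -4.96 ± 0.28 (adjusted p = 1.83e-05) over RPL5, RPL8B, RPS0B, RPL9A, RPS4B, RPS22A, RPS1B and RPL10 to RPS15 at -4.00 ± 0.43. These 20 genes had one sign on all 3 m-nitrophenol arrays. Genes measured on 2 of them are left out of this ranking, although some fell further, such as ELO3, GUA1 and SRL1 (-5.12 ± 0.31).

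After m-nitrophenol 105 of 124 ribosomal protein genes fell (117 adjusted within the list). Their median was -2.92 (camera adjusted p = 3.59e-44, 0.281 with estimated r), and it was -1.26, -3.13 and -4.36 on arrays 1, 2 and 3. 29 of 42 ribosome biogenesis genes fell (32 adjusted within the list). NOP1 fell by 4.76 ± 0.36 and the polymerase I subunit gene RPA49 by 4.75 ± 0.38, with a list median of -2.17 (camera adjusted p = 6.64e-18, none with estimated r). 12 of 26 translation factor genes fell (16 lower and 1 higher adjusted within the list), TEF4 by 2.98 ± 0.39 among them. Their median was -1.16 (camera adjusted p = 4.38e-07, 0.336 with estimated r). 13 of 21 purine and pyrimidine genes fell (14 lower and 1 higher adjusted within the list). GUA1 fell by 5.33 ± 0.43 and the CTP synthase gene URA7 by 3.48 ± 0.37, and the median was -1.71 (camera adjusted p = 4.38e-07, 0.124 with estimated r). 8 of 31 Gcn4-controlled genes fell (8 adjusted within the list), with LYS9 at -2.31, ILV3 at -3.00 and a median of -0.94 (camera adjusted p = 0.000285, 0.312 with estimated r). 5 of 15 aromatic amino acid genes fell (5 adjusted within the list), with ARO10 at -2.47 and a median of -0.71 (camera adjusted p = 0.0114, none with estimated r). 4 of 24 ergosterol genes fell (4 adjusted within the list). The sterol desaturase gene ERG3 fell by 3.69 ± 0.66, and the median was -1.10 (camera adjusted p = 0.000864, 0.236 with estimated r). 8 of 29 cell cycle genes fell (9 adjusted within the list), CLN2 by 3.04 ± 0.34 among them. Their median was -0.64 (camera adjusted p = 0.000212, 0.0562 with estimated r).

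7 lists lay above the other genes in m-nitrophenol. 9 of 30 general stress genes rose (12 adjusted within the list). DDR48 rose by 3.01 ± 0.29 and GRE1 by 3.07 ± 0.48, and the median was 1.32 (camera adjusted p = 1.99e-05, 0.52 with estimated r). 4 of 16 aryl-alcohol and aldehyde dehydrogenase genes rose (9 adjusted within the list), with ARI1 at 2.70, ALD3 at 2.08 and a median of 1.34 (camera adjusted p = 9.87e-05, 0.0562 with estimated r). 7 of 37 proteasome genes rose (7 adjusted within the list), PRE1 by 1.89 ± 0.31 among them. Their median was 0.74 (camera adjusted p = 3.74e-05, 0.52 with estimated r). 9 of 19 diauxic shift markers rose and 1 fell (10 and 1 adjusted within the list), GRE1 and SNZ1 among them. Their median was 1.34 (camera adjusted p = 7.19e-05, 0.419 with estimated r). 7 of 19 autophagy and vacuolar genes rose (10 adjusted within the list). The proteinase inhibitor gene PAI3 rose by 3.34 ± 0.50, and the median was 1.06 (camera adjusted p = 0.000236, 0.232 with estimated r). 7 of 26 iron genes rose and 1 fell (12 and 1 adjusted within the list). The siderophore transporter genes ARN1 and SIT1 rose by 1.99 and 2.13, and the median was 0.68 (camera adjusted p = 0.00259, 0.359 with estimated r). 4 of 31 sulfur amino acid genes rose (2 adjusted within the list). STR3 rose by 3.93 ± 0.64, and the median was 0.69 (camera adjusted p = 0.0142, 0.707 with estimated r). The 21 lists that did not pass had adjusted p from 0.0654 (hexose transport, median 0.49) and 0.0766 (heat shock proteins, 0.32) to 0.98 (trehalose and glycogen). In the multidrug list PDR5, RTA1 (3.00) and PDR10 (2.53) rose and TPO2 fell by 3.19 ± 0.62. The list median was -0.05 (adjusted p = 0.482). INO1, of inositol synthesis, rose by 4.71 ± 0.72, while the fatty acid elongase gene ELO3 of the same list fell by 5.51 ± 0.50. Without replicate 2 of m-nitrophenol 47 genes were higher and 100 lower, without replicate 3 the numbers were 73 and 134, and in both fits the calls of GRE2 (adjusted p = 0.0867 and 0.0564), HSP12 (0.0557 and 0.052), RPL8B (0.0611 and 0.0533) and RPS1B (0.0908 and 0.0752) ended. The calls of HSP26 (0.0684 to 0.206) and FMP16 (0.134 to 0.143) ended without any of the 3 arrays, and that of HSP26 also without replicate 3 of o-nitrophenol (0.0514). A fit without the 3 arrays numbered 1 called 1108 genes higher and 934 lower, with 418 and 490 shared, and the unfolded protein response (median 0.81, adjusted p = 0.0169) and polyamine lists (-0.49, 0.0446) passed.

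After 2 h in 3 mM o-nitrophenol, 702 genes were higher and 951 lower, 641 and 834 of these by at least 2-fold. With each array centred on its median the numbers were 859 and 722. STR3 rose by 7.57 ± 0.52, THI4, of thiazole synthesis for thiamine, by 6.90 ± 0.91, the spore wall gene SPS100 by 6.61 ± 0.35 and the pyruvate decarboxylase gene PDC5 by 6.47 ± 0.45. HSP26 (6.30 ± 1.15), EGO4 (6.27 ± 0.86), GPG1 (6.20 ± 0.56), DDR2 (6.17 ± 0.69), the desiccation gene SIP18 (5.78 ± 0.45) and HSP12 (5.75 ± 0.59) completed the 10 largest rises. The largest falls were those of the elongase gene ELO3 (-5.03 ± 0.41), ERG3 (-4.60 ± 0.66), the cell wall gene UTR2 (-4.37 ± 0.34), the elongation factor gene YEF3 (-4.31 ± 0.65) and GUA1 (-3.99 ± 0.35). The pheromone receptor gene STE3 (-3.92 ± 0.48), the elongase gene ELO2 (-3.85 ± 0.39), SRL1 (-3.85 ± 0.25), the purine salvage gene HPT1 (-3.85 ± 0.45) and the cell wall gene SCW10 (-3.79 ± 0.46) followed. All 20 had one sign on all 3 arrays, with adjusted p from 3.45e-05 for SPS100 to 0.00311 for HSP26. PDC5 is similar in sequence to PDC1 and PDC6, so its probe may read all of them.

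13 lists lay above the other genes in o-nitrophenol. 18 of 30 general stress genes rose (23 adjusted within the list), with a median of 2.72 (camera adjusted p = 3.17e-10, 0.334 with estimated r) and of 3.72, 2.33 and 2.17 on arrays 1, 2 and 3. 15 of 24 heat shock genes rose (15 adjusted within the list). The disaggregase gene HSP104 rose by 4.01 ± 0.27 and HSP31 by 3.46 ± 0.46, and the median was 1.78 (camera adjusted p = 8.33e-09, 0.0138 with estimated r). 19 of 27 oxidative stress genes rose (19 adjusted within the list). The sulfiredoxin gene SRX1 rose by 3.88 ± 0.34 and the glutaredoxin gene GRX1 by 3.48 ± 0.33, with a list median of 2.12 (camera adjusted p = 9.14e-09, 0.122 with estimated r). 16 of 37 proteasome genes rose (21 adjusted within the list), PUP2 by 2.23 ± 0.37 among them. Their median was 1.31 (camera adjusted p = 3.95e-08, 0.377 with estimated r). 10 of 16 aryl-alcohol and aldehyde dehydrogenase genes rose and 1 fell (12 and 1 adjusted within the list). ALD3 rose by 4.84 ± 0.43 and AAD15 by 3.43 ± 0.34, and the median was 2.16 (camera adjusted p = 7.59e-06, 0.0318 with estimated r). 5 of 19 autophagy and vacuolar genes rose and 1 fell (5 and 1 adjusted within the list), PAI3 by 4.56 ± 0.41 among them. Their median was 0.74 (camera adjusted p = 0.00199, 0.209 with estimated r). 6 of 19 diauxic shift markers rose and 1 fell (6 and 1 adjusted within the list), PHM8 by 3.51 ± 0.29 among them. Their median was 0.59 (camera adjusted p = 0.00893, 0.581 with estimated r). 10 of 23 glycolysis and fermentation genes rose and 2 fell (10 and 2 adjusted within the list). PDC6 rose by 3.95 ± 0.41 and the alcohol dehydrogenase gene ADH1 by 1.95 ± 0.26, and the median was 1.14 (camera adjusted p = 0.000258, 0.238 with estimated r). 9 of 34 respiratory chain genes rose and 4 fell (9 and 4 adjusted within the list), QCR8 by 2.29 ± 0.28 among them. Their median was 0.72 (camera adjusted p = 0.00338, 0.229 with estimated r). 5 of 28 hexose transport and glucose-repressed genes rose and 1 fell (5 and 1 adjusted within the list), with the hexokinase gene HXK1 at 4.25. The median was 0.82 (camera adjusted p = 0.0121, 0.678 with estimated r), and it was 2.17, 0.16 and 0.57 on arrays 1, 2 and 3. 8 of 31 sulfur amino acid genes rose and 1 fell (8 and 1 adjusted within the list), with the methionine permease gene MUP1 at 3.34. The median was 1.28 (camera adjusted p = 0.00013, 0.581 with estimated r), and it was 3.77, 0.53 and 0.47 on the 3 arrays. 7 of 23 thiamine, pyridoxine and biotin genes rose and 2 fell (7 and 2 adjusted within the list), with a median of 0.61 (camera adjusted p = 0.0238, none with estimated r). This call ended with the replicate number as a block (median 0.61, adjusted p = 0.056). Among them were THI5, THI11 and THI13, which are near-identical copies. 4 of 19 meiosis markers rose and 1 fell (4 and 1 adjusted within the list), SPO11 by 2.33 ± 0.28 among them. Their median was 0.75 (camera adjusted p = 0.0257, none with estimated r).

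Ribosome biogenesis and translation genes were lower after o-nitrophenol as well. 29 of 42 ribosome biogenesis genes fell (34 adjusted within the list), with a median of -1.47 (camera adjusted p = 1.08e-09, none with estimated r). 17 of 26 translation factor genes fell (17 adjusted within the list), the initiation factor gene TIF5 by 2.49 ± 0.26 among them. Their median was -1.55 (camera adjusted p = 6.02e-07, 0.299 with estimated r). 30 of 124 ribosomal protein genes fell (22 adjusted within the list), with a median of -0.90 (camera adjusted p = 6.27e-06, 0.677 with estimated r). On arrays 1, 2 and 3 it was -2.22, 0.08 and -0.53, so that array 2 did not show the direction. 16 of 21 purine and pyrimidine genes fell and 1 rose (16 and 1 adjusted within the list). GUA1 and URA1 (-2.84) had the lowest p, and the median was -1.94 (camera adjusted p = 4.21e-07, 0.098 with estimated r). 15 of 24 ergosterol genes fell and 1 rose (16 and 1 adjusted within the list). ERG2 fell by 3.20 ± 0.26 and ERG13 by 2.70 ± 0.30, and the median was -1.49 (camera adjusted p = 0.00013, 0.122 with estimated r). 13 of 19 phosphate response genes fell and 1 rose (13 and 2 adjusted within the list), with the acid phosphatase gene PHO12 at -2.73 and a median of -1.08 (camera adjusted p = 0.00305, 0.372 with estimated r). 14 of 29 cell cycle genes fell (18 lower and 1 higher adjusted within the list), with CLN2 at -2.83 and a median of -0.81 (camera adjusted p = 0.000411, 0.0496 with estimated r). 7 of 14 mating genes fell and 1 rose (8 and 1 adjusted within the list), with SAG1 at -3.38 and a median of -0.97 (camera adjusted p = 0.00972, 0.201 with estimated r). The 15 lists that did not pass had adjusted p from 0.106 (cell wall, median -0.47) to 0.999 (beta-oxidation and the TCA cycle). Single members of these changed strongly. The metallothionein genes CUP1-1 and CUP1-2, which are near-identical copies, rose by 5.46 ± 0.41 and 5.42 ± 0.38. CRS5, also a metallothionein gene, rose by 4.17 ± 0.29, while the copper and zinc list had a median of -0.26 (adjusted p = 0.677). FRE1 (-3.07 ± 0.37), SIT1 (-2.55 ± 0.33) and the iron oxidase gene FET3 (-3.07 ± 0.46) fell, with -0.35 (adjusted p = 0.521) for the iron list. Called lists had medians of the called sign on all 3 arrays in the 3 treatments, except the sulfur list in p-nitrophenol and the ribosomal protein list in o-nitrophenol. With an estimated correlation 0 of 17 called lists that could be tested held in p-nitrophenol and 0 of 13 in m-nitrophenol. In o-nitrophenol 3 of 18 held, namely heat shock proteins, aryl-alcohol and aldehyde dehydrogenases, and the cell cycle. Without replicate 1 of o-nitrophenol the calls of ribosomal proteins (median -0.28, adjusted p = 0.204), hexose transport (0.35, 0.206), respiration (0.45, 0.0769), sulfur (0.49, 0.0769), thiamine (0.54, 0.0769) and meiosis (0.67, 0.0593) ended. Without replicate 2 there were 380 higher and 467 lower genes and without replicate 3 381 and 461, with medians of 0.50 for meiosis without replicate 2 and 0.92 for thiamine without replicate 3. Without the 3 arrays numbered 1 there were 1130 and 1493, 685 and 912 of them shared, and the calls of ribosomal proteins (0.0582), hexose transport (0.21), respiration (0.0681), thiamine (0.076) and meiosis (0.075) ended while the sulfur median was 0.49 and the cell wall list passed (-0.83, 0.00379).

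**Figure D1:**
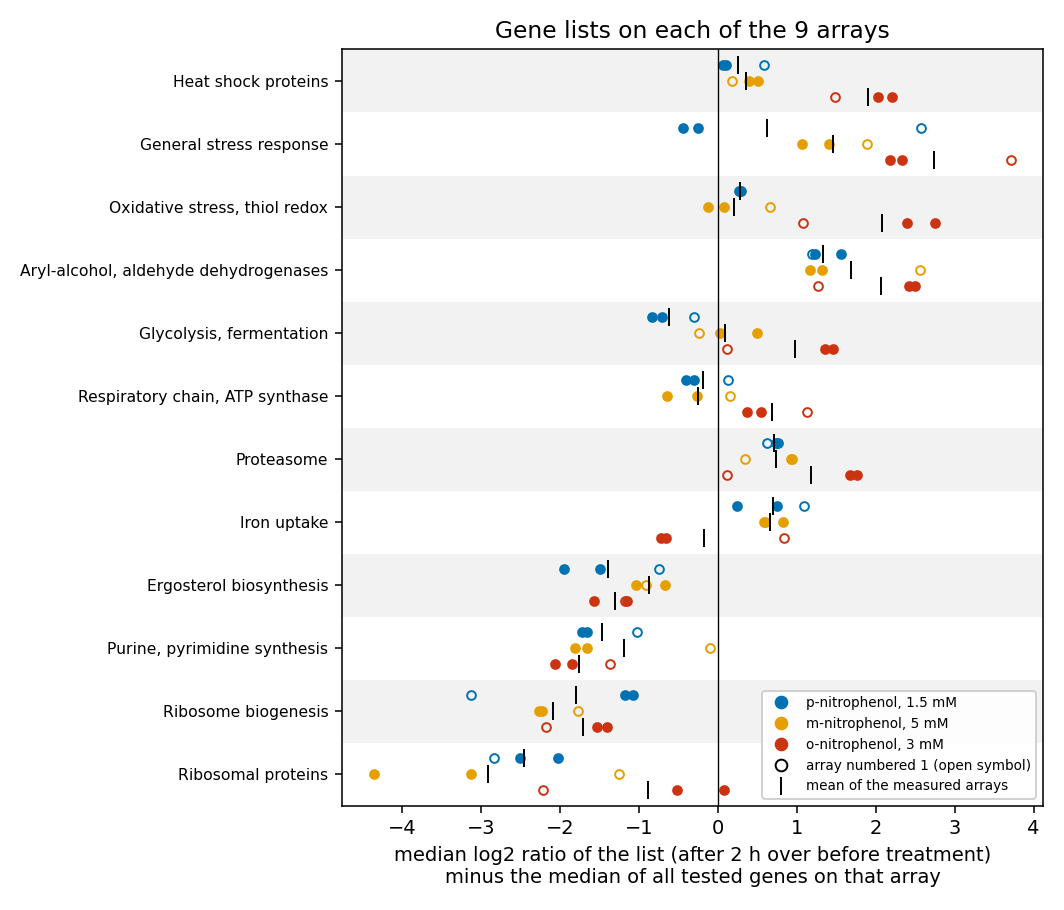
Median log2 ratio of 12 gene lists on each of the 9 arrays (x axis, after 2 h over before treatment, minus the median of all tested genes on that array), with 1 point per array, colours for the isomers, open symbols for the arrays numbered 1 and bars for the mean of the arrays. Heat shock proteins sit at 1.49 to 2.20 on the o-nitrophenol arrays and at 0.07 to 0.58 on the other 6, and ribosomal proteins at -2.22, 0.08 and -0.53 on o-nitrophenol arrays 1, 2 and 3 and at -4.36 to -1.26 on the p- and m-nitrophenol arrays.

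The 3 responses shared many genes. 177 genes were higher and 230 lower after all 3 isomers. These counts were 92 and 147 or 99 and 147 without replicate 2 or 3 of p-nitrophenol, 31 and 65 or 44 and 81 without those of m-nitrophenol, 99 and 158 or 99 and 137 without those of o-nitrophenol, and 424 and 431 without the 3 arrays numbered 1. Between p- and m-nitrophenol 267 higher and 337 lower calls were shared, where independent lists of these sizes would share 54.6 and 58.5. Between p- and o-nitrophenol 321 and 384 were shared (91.1 and 113 if independent), and between m- and o-nitrophenol 236 and 300 (58.0 and 91.8). Without replicate 2 or 3 of an isomer of the pair, 39 to 145 higher and 93 to 205 lower calls were shared by p and m, 131 to 185 and 198 to 257 by p and o, and 36 to 130 and 70 to 197 by m and o. p and m shared 429 higher calls without replicate 1 of o-nitrophenol. The mean log2 ratios correlated across genes at 0.80 for p and m, 0.65 for p and o and 0.64 for m and o, with growth and dye effects common to the arrays included. Calls in opposite directions numbered 1 for p and m, 16 for p and o and 8 for m and o. YHB1, the flavohemoglobin gene of nitric oxide detoxification, fell after each isomer, with -3.20 ± 0.44, -3.59 ± 0.44 and -2.93 ± 0.44 for p-, m- and o-nitrophenol. FRM2, a nitroreductase-like gene, passed in none, with 0.45 ± 0.25, -0.02 ± 0.31 and -0.11 ± 0.25, and neither did the efflux pump gene SNQ2 (1.70 ± 0.79, 1.63 ± 0.79 and -0.44 ± 0.79) or the old yellow enzyme gene OYE2 (1.59 ± 0.55, 0.91 ± 0.55 and 0.39 ± 0.55), although OYE2 passed in p-nitrophenol with the replicate number as a block. OYE3 rose in p- and o-nitrophenol (1.28 ± 0.35 and 1.92 ± 0.35), with -0.04 ± 0.43 in m-nitrophenol. The thioredoxin gene TRX2 rose by 2.10 ± 0.52 and 3.16 ± 0.52 in p- and o-nitrophenol, the glutathione transferase gene GTT2 by 1.82 ± 0.39 and 2.58 ± 0.39, and RPN4, the regulator of proteasome genes, by 1.32 ± 0.35 and 1.43 ± 0.35. Their m-nitrophenol values of 1.60 ± 0.52, 1.37 ± 0.48 and 0.49 ± 0.43 did not pass. HSP12 rose after all 3 and HSP26 after m- and o-nitrophenol, while HSP26 had 1.29 ± 1.15 in p-nitrophenol, with an SD of 4.02 over the 3 arrays. In p-nitrophenol HSP26 turned to -1.02 without the 3 arrays numbered 1 (adjusted p = 0.00888) and to -0.998 in the low-power scans alone (adjusted p = 0.0483). These single-gene calls were sensitive to arrays. In p-nitrophenol OYE3 ended without replicate 1 or 2 (adjusted p = 0.123 and 0.098), TRX2 (0.0962 and 0.0669) and RPN4 (0.155 and 0.127) without replicate 2 or 3, GTT2 without replicate 3 (0.0684) and HSP12 without replicate 1 (0.0656), and in o-nitrophenol RPN4 without replicate 2 or 3 (0.0714 and 0.0966). PMA1, the plasma membrane proton pump gene, had values only on the arrays numbered 1 (-2.40, -1.68 and -0.70 for p-, m- and o-nitrophenol) and was not tested, and HBN1 has no named probe on the array.

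**Figure D2:**
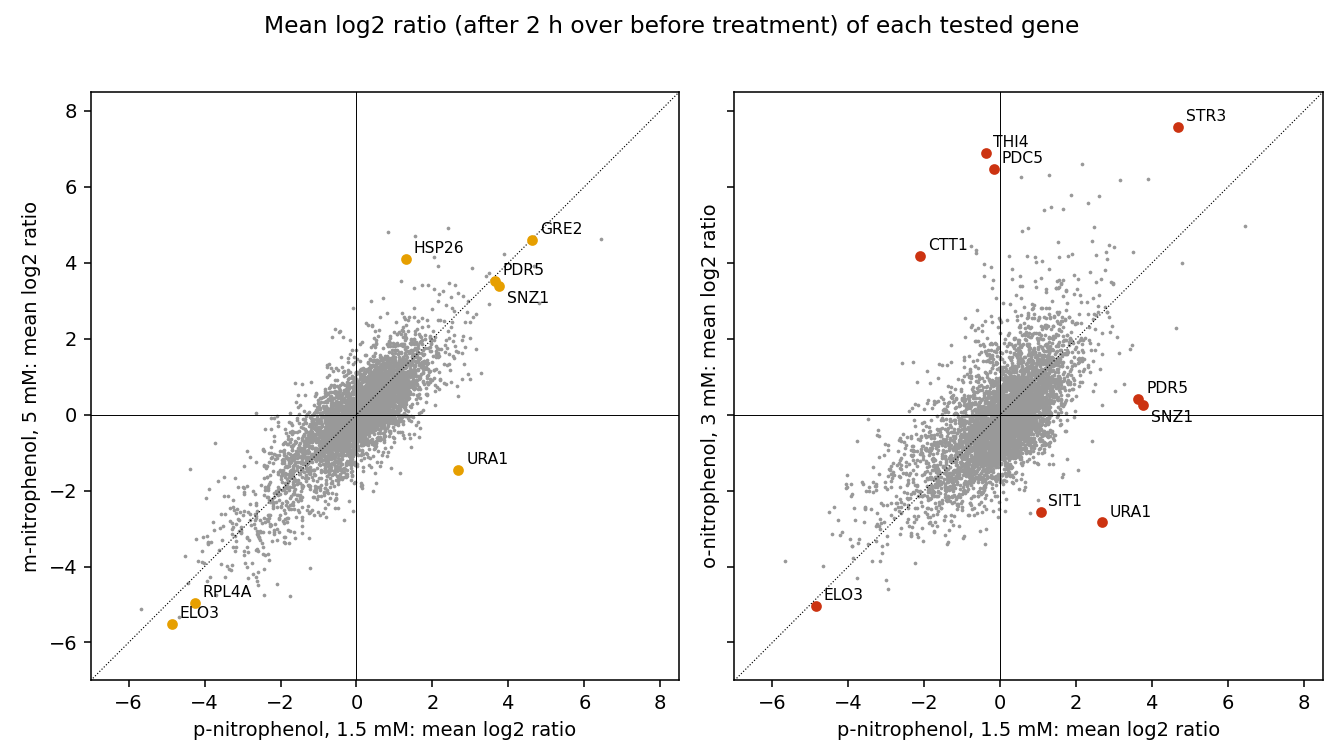
Mean log2 ratio of each tested gene after m-nitrophenol (left) and o-nitrophenol (right) against p-nitrophenol, with 1 point per gene, a dotted line of equal values and selected genes in colour. PDR5 and SNZ1 lie near the line on the left and far below it on the right, where PDC5, THI4 and CTT1 lie far above it.

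The isomers differ in where the nitro group sits, opposite the hydroxyl group in p-nitrophenol, next to it in o-nitrophenol and one carbon further along the ring in m-nitrophenol. They were also used at different concentrations, so isomer and dose cannot be told apart in any difference that follows. A moderated F test called 54 genes that differed among the 3 groups, and 41 of them, with no others, when it was computed from each gene's own numbers of arrays. It called 12 or 5 without replicate 2 or 3 of p-nitrophenol, 14 without either of m-nitrophenol, 3 or 4 without those of o-nitrophenol, 236 or 147 without replicate 1 of p- or o-nitrophenol, and 1347 without the 3 arrays numbered 1. Between m- and p-nitrophenol, at 5 and 1.5 mM, 1 gene differed. URA1 was lower in m-nitrophenol by -4.14 ± 0.44 (adjusted p = 0.021), with 2.69 ± 0.28 in p-nitrophenol and -1.45 ± 0.34 in m-nitrophenol on the 2 arrays that measured it, and it was singled out after its values were seen because it lacks a value on m-nitrophenol array 1. No gene was called higher by limma, and 364 genes had an unadjusted p under 0.05 in either direction. This does not show that both isomers act alike, since only 164 genes had a 95% interval of the difference within 2-fold. PDR5 differed by -0.13 with an interval from -1.39 to 1.14, HSP26 by 2.80 (-0.80 to 6.41) and OYE3 by -1.33 (-2.58 to -0.07, adjusted p = 0.678). YHB1 differed by -0.39 ± 0.62, SNQ2 by -0.07 ± 1.12, FRM2 by -0.47 ± 0.40, OYE2 by -0.68 ± 0.78, HSP12 by 0.82 ± 0.84, TRX2 by -0.50 ± 0.73, GTT2 by -0.44 ± 0.62 and RPN4 by -0.83 ± 0.55, none past the threshold.

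As whole lists, 15 groups differed between m- and p-nitrophenol by camera, although none of their members passed over all genes. 11 were higher and 4 lower in m-nitrophenol. General stress genes were higher in m-nitrophenol by a median of 0.90 (camera adjusted p = 5.89e-05, 0.685 with estimated r), and genes of the unfolded protein response by 0.90 (camera adjusted p = 3.07e-05, 0.428 with estimated r). The medians were 0.73 (camera adjusted p = 0.000262, 0.685 with estimated r) for hexose transport, 0.51 (camera adjusted p = 0.0253, 0.685 with estimated r) for diauxic shift markers and 0.47 (camera adjusted p = 0.0378, 0.785 with estimated r) for trehalose and glycogen. Glycolysis was at 0.55 (camera adjusted p = 3.07e-05, 0.375 with estimated r), and 4 of its members were higher adjusted within the list, PDC6 first. Fatty acid and phospholipid synthesis was at 0.55 (camera adjusted p = 0.0206, 0.375 with estimated r) and ergosterol synthesis at 0.38 (camera adjusted p = 0.0153, 0.375 with estimated r). The lists of the TCA cycle (-0.04, 0.754), respiration (0.04, 0.721) and beta-oxidation (0.21, 0.243) did not pass. The phosphate response was higher by 0.46 (camera adjusted p = 0.000484, 0.375 with estimated r), with PHO89 and GIT1 past the threshold adjusted within the list. Cell wall genes were at 0.33 (camera adjusted p = 0.0084, 0.685 with estimated r), and mating genes at 0.33 (camera adjusted p = 0.00128, 0.375 with estimated r) with 3 members higher adjusted within the list. Of the lists that were lower, ribosome biogenesis was at -0.63 (camera adjusted p = 1.89e-05, none with estimated r) and ribosomal proteins at -0.51 (camera adjusted p = 0.000943, 0.863 with estimated r), while translation factors, at -0.05 (adjusted p = 0.879), did not pass. Aromatic amino acid genes were at -0.65 (camera adjusted p = 0.00341, none with estimated r). Gcn4-controlled genes were at -0.52 (camera adjusted p = 0.000545, 0.375 with estimated r), with HIS7 (-2.28) lower adjusted within the list. Without replicate 2 of p-nitrophenol 10 of these 15 calls ended (adjusted p from 0.0551 to 0.408), and 5 ended without replicate 3 of m-nitrophenol (0.0562 to 0.274), 3 without replicate 1 of m-nitrophenol (0.0693 to 0.214), 2 without replicate 3 of p-nitrophenol (0.122 and 0.506) and 1 without replicate 1 of p-nitrophenol (0.162). With the left-out isomer and replicate in brackets, medians ranged from 0.42 (p 2) to 1.51 (p 1) for general stress, 0.06 (p 3) to 1.29 (p 1) for trehalose, 0.23 (p 3) to 0.71 (p 1) for the cell wall, 0.22 (p 2) to 0.79 (p 1) for ergosterol, 0.24 (p 1) to 0.55 (p 3) for fatty acids, 0.33 (m 3) to 0.86 (p 1) for glycolysis, 0.24 (p 2) to 1.11 (p 1) for hexose transport, 0.19 (p 3) to 0.67 (p 1) for the diauxic list, -0.94 (p 1) to -0.26 (p 2) for Gcn4-controlled genes, -1.28 (p 1) to -0.18 (p 2) for aromatic amino acids, 0.21 (p 3) to 0.87 (p 1) for phosphate, -0.95 (p 1) to -0.49 (p 3) for ribosome biogenesis, 0.20 (p 2) to 0.50 (p 3) for mating and -1.17 (m 1) to 0.13 (m 3) for ribosomal proteins, and the URA1 call ended without replicate 2 or 3 of p- or m-nitrophenol or replicate 3 of o-nitrophenol, in the low-power scans alone and with only the 6 arrays of the contrast in the fit. A fit without the 3 arrays numbered 1 called 145 genes higher and 147 lower and no longer the fatty acid list (0.117), but sulfur (median -0.70, adjusted p = 0.00253) and copper and zinc (0.64, 0.0273).

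Between o- and p-nitrophenol, at 3 and 1.5 mM, 42 genes were higher and 18 lower after o-nitrophenol. With each array centred on its median there were 69 and 12. PDC5 was higher by 6.63 ± 0.63 (adjusted p = 0.00188) and CTT1, the cytosolic catalase gene, by 6.28 ± 0.83 (adjusted p = 0.00895), since it fell to -2.11 in p-nitrophenol and rose to 4.17 in o-nitrophenol. SPS100 (4.45 ± 0.49), PDC6 (4.38 ± 0.58), the aldehyde dehydrogenase gene ALD3 (4.26 ± 0.61) and YRO2, a plasma membrane protein gene (4.18 ± 0.71), were the other large positive differences named. URA1 was lower by -5.52 ± 0.39 (adjusted p = 0.000615), with 2.69 in p-nitrophenol and -2.84 in o-nitrophenol. SIT1 (-3.61 ± 0.46), SNZ1 (-3.51 ± 0.58), the pentose phosphate gene SOL3 (-3.26 ± 0.40), the aldehyde dehydrogenase gene ALD6 (-3.24 ± 0.60) and PDR5 (-3.23 ± 0.57, adjusted p = 0.027) were lower too. PDR5, which rose in p-nitrophenol, had a mean of 0.41 ± 0.40 in o-nitrophenol. These 12 genes were named among those with values on all 6 arrays that did not overlap between both isomers.

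Heat shock genes were higher by a median of 1.84 (camera adjusted p = 1.66e-10, 0.00865 with estimated r) after o-nitrophenol than after p-nitrophenol. 3 of 24, HSP104, SSA4 and HSP30 (4.98 ± 0.93, on 5 arrays), passed (15 adjusted within the list). General stress genes were higher by 2.07 (camera adjusted p = 4.14e-12, 0.393 with estimated r). 2 of 30, CTT1 and SIP18, passed (12 adjusted within the list). Oxidative stress genes were higher by 1.26 (camera adjusted p = 4.19e-08, 0.174 with estimated r). 4 of 27 passed (7 adjusted within the list), among them SRX1 with 4.12 ± 0.48, measured on arrays 2 and 3 only. Glycolysis and fermentation genes were higher by 1.54 (camera adjusted p = 4.92e-11, 0.0881 with estimated r). 6 of 23 passed (9 adjusted within the list), ADH1 with 2.62 ± 0.37 among them. Respiratory chain genes were higher by 0.87 (camera adjusted p = 2.61e-07, 0.0881 with estimated r). 1 of 34, QCR6, passed with 2.13 ± 0.39 (5 adjusted within the list). Polyamine and ion genes were higher by 0.55 (camera adjusted p = 0.000147, 0.0881 with estimated r). 4 of 25 passed (4 adjusted within the list), TPO2 with 3.96 ± 0.72 among them. Ribosomal protein genes lay higher by 1.49 (camera adjusted p = 6.48e-18, 0.552 with estimated r), with no single one of 124 past the threshold over all genes or over the list alone. Trehalose and glycogen genes lay higher by 0.81 (camera adjusted p = 0.0416, 0.888 with estimated r) and hexose transport by 0.79 (camera adjusted p = 0.00162, 0.888 with estimated r), the latter with 1 member adjusted within the list. The trehalose median was 2.29, -0.80 and -0.67 on o-nitrophenol arrays 1, 2 and 3 and 0.77, -1.37 and -1.33 on the p-nitrophenol arrays. Meiosis markers lay higher by 0.42 (camera adjusted p = 0.0174, none with estimated r), SPS100 alone past the threshold in both counts. Iron genes were lower by -0.99 (camera adjusted p = 0.00351, 0.393 with estimated r). 2 of 26, SIT1 and CCC2, passed (8 adjusted within the list). HSP12 (3.16 ± 0.84), HSP26 (5.01 ± 1.63), TRX2 (1.05 ± 0.73), GTT2 (0.77 ± 0.56), RPN4 (0.11 ± 0.50) and OYE3 (0.64 ± 0.50) did not pass in this difference. Neither did OYE2 (-1.20 ± 0.78), SNQ2 (-2.14 ± 1.12), FRM2 (-0.56 ± 0.36) or YHB1 (0.27 ± 0.62). The count of 42 and 18 fell to 4 and 2 without replicate 2 or 3 of p-nitrophenol, 16 and 4 or 6 and 3 without replicate 2 or 3 of o-nitrophenol, and 20 and 5 or 21 and 5 without replicate 2 or 3 of m-nitrophenol, and it was 112 and 99 without replicate 1 of p-nitrophenol and 79 and 95 without replicate 1 of o-nitrophenol. PDC5, SPS100, SOL3 and URA1 passed in every such fit and the other 8 named genes were lost in at least 1 (adjusted p at most 0.148), as were hexose transport (0.0609 and 0.135 without p 2 or o 1), meiosis (0.0987 without p 2) and trehalose (0.0526 to 0.906 without m 1, p 2, p 3 or o 1), with medians of 1.61 (p 2) to 3.27 (p 1) for general stress, -0.09 (o 1) to 1.69 (p 1) for trehalose, 0.34 (p 2) to 1.22 (p 1) for hexose transport, -1.53 (o 1) to -0.64 (o 2) for iron, 0.55 (m 1) to 1.10 (o 3) for polyamines and 0.40 (o 2) to 0.66 (p 3) for meiosis. A fit without the 3 arrays numbered 1 called 462 genes higher and 621 lower, with all 42 and 18 among them, and the proteasome (median 0.88, adjusted p = 8e-06), sulfur (-0.65, 0.0135) and copper lists (0.63, 0.0341). With the replicate number as a block, 105 genes were higher and 81 lower, again with all 42 and 18 among them.

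Between o- and m-nitrophenol, at 3 and 5 mM, 21 genes were higher and 16 lower after o-nitrophenol. With each array centred on its median there were 52 and 14. PDC5 was higher by 6.85 ± 0.63 and FSH1, a serine hydrolase gene, by 4.25 ± 0.41 (both adjusted p = 0.00225). YRO2 (4.15 ± 0.71), CUP1-2 (4.05 ± 0.54), CUP1-1 (3.96 ± 0.57) and RIE1 (3.55 ± 0.54) were also higher. ALD6 (-3.15 ± 0.60), SNZ1 (-3.14 ± 0.58), PDR5 (-3.11 ± 0.57, adjusted p = 0.0433), ARN1 (-2.51 ± 0.42) and SOL3 (-2.11 ± 0.40) were lower, named by the same rule.

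Heat shock genes were also higher after o- than after m-nitrophenol, by a median of 1.56 (camera adjusted p = 7.14e-07, 0.0275 with estimated r). 2 of 24, HSP104 and HSP30 (6.40 ± 0.93, on 5 arrays), passed (9 adjusted within the list). Oxidative stress genes were higher by 1.44 (camera adjusted p = 2.39e-08, 0.191 with estimated r). 1 of 27, SRX1, measured on arrays 2 and 3 only, passed (11 adjusted within the list). Respiratory chain genes were higher by 0.86 (camera adjusted p = 4.97e-06, 0.191 with estimated r). 1 of 34, QCR6, passed (5 adjusted within the list). Glycolysis genes were higher by 0.80 (camera adjusted p = 0.000193, 0.249 with estimated r), PDC5 and PDC1 past the threshold in both counts. Polyamine and ion genes were higher by 0.34 (camera adjusted p = 0.014, 0.249 with estimated r). HSP30, YRO2 and TPO2 passed (4 higher and 1 lower adjusted within the list). Ribosomal protein genes were higher by 1.93 (camera adjusted p = 1.15e-27, 0.378 with estimated r). 2 of 124 passed, RPL4A with 2.20 ± 0.39 and RPS29A with 3.47 ± 0.59 (28 adjusted within the list). In 4 lists that were higher no member passed over all genes. General stress was at 1.43 (camera adjusted p = 4.79e-05, 0.628 with estimated r), with 4 members higher and 1 lower adjusted within the list, and ribosome biogenesis was at 0.54 (camera adjusted p = 0.0105, none with estimated r). Gcn4-controlled amino acids were at 1.05 (camera adjusted p = 0.000193, 0.249 with estimated r) and aromatic amino acids at 0.72 (camera adjusted p = 0.0362, none with estimated r). Iron genes were lower by -1.35 (camera adjusted p = 0.000225, 0.249 with estimated r). 2 of 26 passed, SIT1 with -4.68 ± 0.52 and ARN1 (13 lower and 2 higher adjusted within the list). Mating genes were lower by -0.74 (camera adjusted p = 0.00338, 0.191 with estimated r), with 4 members adjusted within the list, and the unfolded protein response by -0.63 (camera adjusted p = 0.00596, 0.628 with estimated r), with 2. The phosphate response was lower by -0.78 (camera adjusted p = 0.0433, 0.628 with estimated r) (1 higher and 1 lower adjusted within the list), although its member PHM8 was higher by 2.19 ± 0.38. HSP12 (2.34 ± 0.84), HSP26 (2.20 ± 1.63), TRX2 (1.56 ± 0.73), GTT2 (1.21 ± 0.62), RPN4 (0.94 ± 0.55) and OYE3 (1.96 ± 0.56) did not pass here. OYE2 (-0.52 ± 0.78), SNQ2 (-2.07 ± 1.12), FRM2 (-0.10 ± 0.40) and YHB1 (0.66 ± 0.62) did not pass either. The count of 21 and 16 was 3 and 0 without replicate 2 of m-nitrophenol, 2 and 0 without replicate 3, 3 and 2 or 3 and 0 without replicate 2 or 3 of o-nitrophenol, 11 and 1 or 10 and 1 without replicate 2 or 3 of p-nitrophenol, and 90 and 70, 62 and 24 or 143 and 150 without replicate 1 of p-, m- or o-nitrophenol. PDC5 and FSH1 passed in every such fit and the other 9 named genes were lost in at least 1 (adjusted p at most 0.236), as were general stress and the unfolded protein response (without o 1, 0.0737 both), polyamines (o 1 or m 3, 0.0737 and 0.115), aromatic amino acids (o 1, o 2 or m 3, 0.0638 to 0.123), phosphate (o 1, m 1 or m 3, 0.0578 to 0.176) and ribosome biogenesis (m 3 or o 3, 0.0658 and 0.0577), with medians of 0.71 (o 1) to 1.73 (o 3) for general stress, 0.54 (o 1) to 1.09 (m 1) for respiration, 0.43 (o 2) to 1.01 (o 1) for glycolysis, 0.69 (o 1) to 1.21 (o 3) for Gcn4-controlled genes, 0.09 (m 3) to 0.65 (o 2) for polyamines, 0.33 (o 2) to 0.62 (o 3) for ribosome biogenesis and 1.28 (m 3) to 2.60 (m 1) for ribosomal proteins. A fit without the 3 arrays numbered 1 called 467 genes higher and 587 lower, with all 21 and 16 among them, not the phosphate list (median -0.49, adjusted p = 0.185), and the aryl-alcohol (0.83, 0.0133) and proteasome lists (0.85, 0.000161).

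22 genes passed in the same direction against both other isomers. There were 2 to 4 without replicate 2 or 3 of any isomer, 69, 29 and 108 without replicate 1 of p-, m- and o-nitrophenol, and 576, all 22 among them, without these 3 arrays. The 15 that were higher after o-nitrophenol included 2 pyruvate decarboxylase genes (PDC1 and PDC5), CUP1-1 and CUP1-2, the chaperone genes HSP104 and HSP30, SRX1, the calcium pump gene PMC1 and TPO2. FSH1, PHM8, QCR6, RGS2, RIE1 and YRO2 were the others. The 7 that were lower were ALD6, PDR5, PNO1, SIT1, SNZ1, SOL3 and YOR385W. Independent lists of these sizes would share 0.173 higher and 0.0565 lower genes, and 100 simulations with no effect and the same shared o-nitrophenol arrays gave at most 1. With no effect few genes pass in either difference, so that overlap is small in advance and does not weigh the 22. The 2 differences correlated across genes at 0.762, against 0.487 simulated, with a covariance of 0.749 against 0.218. Part of the excess may come from the shared arrays, since 3 arrays cannot be split into parts of at least 2.

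**Figure D3:**
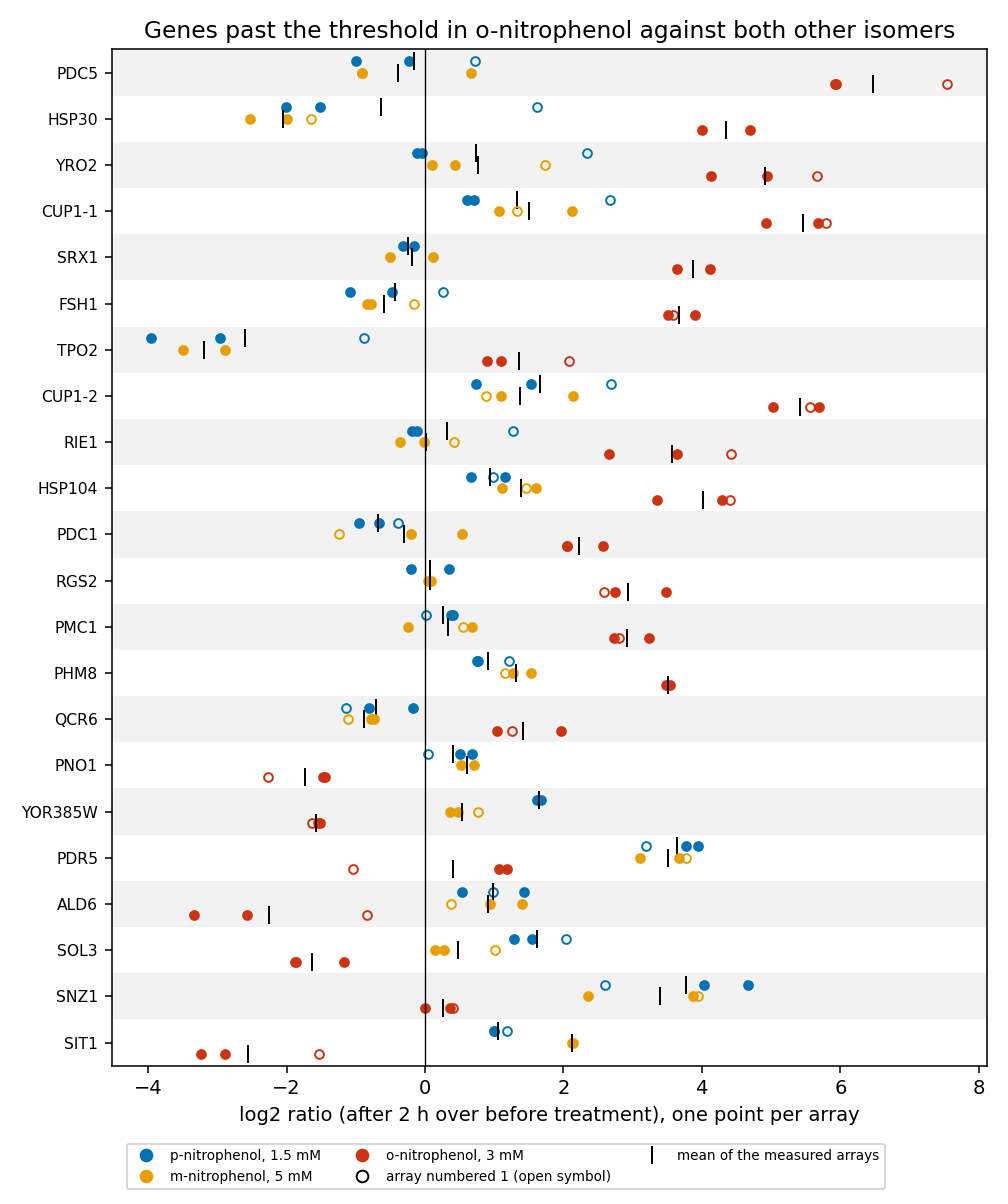
Log2 ratio (x axis, after 2 h over before treatment) of the 22 genes past the threshold in o-nitrophenol against both other isomers, with 1 point per array that measured the gene, colours for the isomers, open symbols for the arrays numbered 1 and bars for the mean of the measured arrays. The o-nitrophenol arrays lie to the right of the others for 15 genes and to the left for 7.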

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

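The splits of the arrays into other groups, except the 36 that part same-numbered arrays and those of arrays 2 and 3 alone, and the fits of the low-power scans alone or without 1 array were planned. The other tests in this part, and the use of those fits to weigh explanations, were chosen after the results were seen. Results are listed because the test of a difference between isomers passed its threshold.

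54 genes differed among the 3 isomers. In 1 of 100 splits of the 9 arrays, the real one, so many genes were called, the highest of the others gave 28, and a split by replicate number gave 3. Computed from each gene's own numbers of arrays it gave 41 genes, against 47 in the highest other of the same 100 splits. Of all 36 splits that part same-numbered arrays 2 gave as many, the other with 121. That split exchanges the arrays numbered 1 of p- and m-nitrophenol and points to a structure of the arrays, so chance is not excluded. The count itself ranged from 3 to 236 when 1 array was left out, and it was 185 with a replicate block. m- and p-nitrophenol differed in 1 gene, URA1, lower in m-nitrophenol, with 0 as the highest of the other splits. o- and p-nitrophenol differed in 42 genes higher and 18 lower after o-nitrophenol, 60 in all against 0 in the highest other split, the 3 others that also part all same-numbered arrays included. o- and m-nitrophenol differed in 21 and 16 genes, 37 in all against 29. With 10 splits per pair, 1 as large is the fewest possible, too few for a share under 0.05.

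For o minus p the named differences were 6.63 for PDC5, 6.28 for CTT1, 4.45 for SPS100, 4.38 for PDC6, 4.26 for ALD3 and 4.18 for YRO2, and -5.52 for URA1, -3.61 for SIT1, -3.51 for SNZ1, -3.26 for SOL3, -3.24 for ALD6 and -3.23 for PDR5. For o minus m they were 6.85 for PDC5, 4.25 for FSH1, 4.15 for YRO2, 4.05 for CUP1-2, 3.96 for CUP1-1 and 3.55 for RIE1, and -3.15 for ALD6, -3.14 for SNZ1, -3.11 for PDR5, -2.51 for ARN1 and -2.11 for SOL3.

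The list medians that differed for m minus p (0 of the 13 that could be tested held with estimated correlation) were 0.90 for general stress, 0.47 for trehalose, 0.90 for the unfolded protein response, 0.33 for the cell wall, 0.38 for ergosterol, 0.55 for fatty acids, 0.55 for glycolysis, 0.73 for hexose transport, 0.51 for the diauxic list, -0.52 for Gcn4-controlled genes, -0.65 for aromatic amino acids, 0.46 for phosphate, -0.63 for ribosome biogenesis, 0.33 for mating and -0.51 for ribosomal proteins. For o minus p (1 of 10 held) they were 1.26 for oxidative stress, 1.84 for heat shock, 2.07 for general stress, 0.81 for trehalose, 0.87 for respiration, 1.54 for glycolysis, 0.79 for hexose transport, -0.99 for iron, 0.55 for polyamines, 0.42 for meiosis and 1.49 for ribosomal proteins. For o minus m (1 of 12 held) they were 1.44 for oxidative stress, 1.56 for heat shock, 1.43 for general stress, -0.63 for the unfolded protein response, 0.86 for respiration, 0.80 for glycolysis, 1.05 for Gcn4-controlled genes, 0.72 for aromatic amino acids, -1.35 for iron, -0.78 for phosphate, 0.34 for polyamines, 0.54 for ribosome biogenesis, -0.74 for mating and 1.93 for ribosomal proteins.

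The first pattern is o-nitrophenol outside both other isomers. A response rising with the concentration used would put o-nitrophenol, at the middle dose, between the others. This failed for 22 genes outside both in 1 direction (2 to 4 without replicate 2 or 3 of any isomer). Of those 36 splits 32 mix o-nitrophenol arrays with others and gave at most 1, but mixing widens the spread. The other 4 gave 10 to 48, so the splits do not test dose order. The sparsely measured arrays numbered 1 are excluded as the whole cause, since arrays 2 and 3 alone called 576 genes outside both, against 79 in the highest other of their 15 splits. One common response that differs between isomers only in strength stays open. 12 genes were called in opposite directions by 2 isomers with the difference itself past the threshold, but growth since the RNA taken before treatment can turn a sign. Isomer and dose relative to toxicity cannot be told apart in this design, and an effect of the isomer itself stays open as a hypothesis.

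The second pattern is that the arrays numbered 1 stood apart from arrays 2 and 3. Spot noise unrelated to gene function is excluded, since at least 10 lists deviated on each array (17 of 36 for p-, 10 of 30 for m- and 15 of 36 for o-nitrophenol) where chance gives 1.8, 1.5 and 1.8. A swap of the o-nitrophenol label with p- or m-nitrophenol is not favoured, since 0 or 4 genes would differ among isomers against 41. The p- and o-nitrophenol arrays were each closer to their own group than to the other's, by 0.26 ± 0.04 and 0.19 ± 0.05 (mean log2 distance, standard error over genes), and the m-nitrophenol array was closer to its own than to o-nitrophenol by 0.47 ± 0.06. A swap between p- and m-nitrophenol stays open. The m-nitrophenol array was closer to its own group by 0.18. That of p-nitrophenol was closer to m-nitrophenol by 0.35, and 121 genes would differ. A wrong isomer label on a single array numbered 1 stays open, as does an untested difference in culture or growth. All 3 were nearest to m-nitrophenol (p-nitrophenol 0.877 against 1.22 to its own group, o-nitrophenol 1.38 against 1.44). Arrays 2 and 3 of a group lay 0.46 to 0.50 apart, but the genes were chosen on these arrays.

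The third pattern is that ribosomal protein genes fell less after o-nitrophenol by camera, though not with estimated correlation (adjusted p = 0.552 for o minus p and 0.378 for o minus m). Saturated bright spots of the high-power scan are excluded as the whole cause, since over the 58 of these genes with both scans of all arrays 2 and 3 the differences were 1.71 and 3.22 in the low-power scans, against 1.57 and 2.88 in the high-power scans. Whether the low-power scans saturate was not examined. Spread between cultures of one isomer stays open, since 2 of the 3 o-nitrophenol arrays lay above all 6 others and the array numbered 1 did not. Without that array the differences were 2.09 against p-nitrophenol and 2.54 against m-nitrophenol, and without all 3 arrays numbered 1 they were 1.83 and 3.21. The isomer or its dose remains a candidate explanation that was not tested apart from these.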

How the results depend on the processing

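All settings here were planned except leaving out the 3 arrays numbered 1, adding probes with no gene name and the F test from each gene's own numbers of arrays (41 genes), which were chosen after seeing the data. The number of genes past the threshold depended more on which arrays entered and how they were weighted than on scaling. Over all settings 435 counts stayed within 1.5 times their value and 261 moved. Of single-gene results 2216 kept direction and threshold side, 135 lost the call, 44 gained one and 2 reversed. Of list results 1993 kept both, 261 lost the call and 3 lost it and reversed. No count moved with a robust prior, with no filter (5363 genes), with probes of one gene not averaged (5237) or with probes of no gene name added (5514).

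Counts are given as higher and lower. With array weights they were 1325 and 1108 for p-nitrophenol, 1109 and 982 for m-nitrophenol, 1126 and 1526 for o-nitrophenol, 133 and 130 for m minus p, 529 and 748 for o minus p, 454 and 572 for o minus m, 1587 by the F test and 462 and 503 in all 3. Without the 3 arrays numbered 1 they were 1150 and 996, 1108 and 934, 1130 and 1493, 145 and 147, 462 and 621, 467 and 587, 1347, and 424 and 431 in the same order. Array weights gave the arrays numbered 1 low weight (0.26, 0.43 and 0.20 for p-, m- and o-nitrophenol).

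With all 18 scans and the array as a random block, 1 gene was higher for m minus p, 131 and 118 differed for o minus p, 127 and 99 for o minus m and 278 by the F test. In the high-power scans alone o minus m gave 11 and 1 and the F test 30. In the low-power scans alone 318 genes were lower in m-nitrophenol, 604 in o-nitrophenol and 140 in all 3, m minus p gave 2 and 0, 49 were lower for o minus p, o minus m gave 79 and 67 and the F test 148. The 306 genes with both scans of all 9 arrays gave 83 and 33, 48 and 27, and 71 and 27 for p-, m- and o-nitrophenol, 0 lower for m minus p, 4 and 1 for o minus p, 2 and 1 for o minus m, 6 by the F test and 29 and 8 in all 3, since fewer genes were tested. Centring each array gave 69 higher for o minus p and 52 for o minus m. Quantile scaling gave 638 higher in m-nitrophenol, 1 higher for m minus p and 26 lower for o minus m. Scale normalization gave 685 higher in m-nitrophenol and 37 and 27 for o minus m. With only the arrays of the contrast 639 genes were higher in m-nitrophenol, o-nitrophenol gave 461 and 591, m minus p 0 lower, o minus p 17 and 5 and o minus m 10 and 3. Except for the fewer genes, arrays or weights named, the cause was not tested.

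8 of 9 arrays correlated best with their own replicate number (other numbers -0.2835 to 0.1115), a hint and not the design. With a replicate block p-nitrophenol gave 862 and 769, m-nitrophenol 597 and 652, o-nitrophenol 864 and 1187, m minus p 0 lower, o minus p 105 and 81, o minus m 96 and 74, the F test 185, and all 3 gave 266 higher and 340 lower. The block ended the thiamine call in o-nitrophenol (0.056) and added OYE2 in p-nitrophenol (0.00445), and it changed no other list or named gene called in p-nitrophenol, o-nitrophenol or o minus p.

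Leaving out 1 array at a time, the counts ranged from 211 to 913 higher and 288 to 789 lower for p-nitrophenol, 47 to 637 and 100 to 640 for m-nitrophenol, 380 to 815 and 461 to 1110 for o-nitrophenol, 0 to 2 and 0 to 2 for m minus p, 4 to 112 and 2 to 99 for o minus p, 2 to 143 and 0 to 150 for o minus m, 3 to 236 by the F test, and 31 to 252 and 65 to 268 in all 3. The 22 genes outside both other isomers numbered 6 in the high-power scans alone, 58 in the low-power scans alone, 78 with a replicate block and 606 with array weights. The lowest counts of a treatment came without its array 2 or 3. HSP26 in p-nitrophenol reversed to -0.998 in the low-power scans alone and to -1.02 without the arrays numbered 1. fry kept 35 of the 83 list calls it could test and camera with estimated correlation 5 of 83. The low-power scans alone lost 30 of 94. Nitrogen catabolism in p-nitrophenol, at a median of -0.44, went up by fry, with no call (adjusted p = 0.408). Leaving out 1 array, the ribosomal protein median for m minus p ranged from -1.17 to 0.13, positive without m-nitrophenol replicate 3, and the trehalose median for o minus p from -0.0855 to 1.69, negative without o-nitrophenol replicate 1.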

Other observations

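The genes in this part and the test of thiamine genes were chosen after the values were seen. OSI1, a reductase gene, had the largest mean of all tested genes in p-nitrophenol, 6.43 ± 0.39 (adjusted p = 0.000298), with 4.63 ± 0.39 in m-nitrophenol and 4.96 ± 0.39 in o-nitrophenol, and it was measured on arrays 2 and 3 only.

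Between p- and o-nitrophenol 16 genes were called in opposite directions. ACM1, CTR86, MRPS8, SIT1, SOL3, SPG5, URA1, YHL049C, YKT6, YOR019W and YOR385W rose after p-nitrophenol and fell after o-nitrophenol, while AGP1, CTT1, HST2, PFK2 and SSA4 went the other way. Between m- and o-nitrophenol 8 were, with COX23, DAS1, MCD4, SIT1 and STE50 higher after m-nitrophenol and lower after o-nitrophenol, and AGP1, HSP30 and OPT1 the other way. Of 418 tested probes with no gene name 104 were higher and 25 lower after o-nitrophenol, against 35 and 40 after p-nitrophenol and 30 and 32 after m-nitrophenol.

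PDC5 and THI4, both known to rise when thiamine is short, were among the largest rises after o-nitrophenol. A response to low thiamine was tested as a hypothesis on 15 other thiamine-repressed genes. 7 of the 15 were higher, THI6, THI20, PET18 and the near-identical copies THI5, THI11, THI12 and THI13, which count as little more than 1 observation. The median was 0.87, and 2 were lower, PHO3 (-2.38, with -3.08 and -3.06 in p- and m-nitrophenol) and THI7 (-0.92, with -0.998 and 0.18). The 7 had 0.15 to 1.03 and 0.12 to 1.71 in these isomers, so neither direction was confined to o-nitrophenol. Members passed in both directions, so a response to low thiamine stays open for part of these rises.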
